A study of Mus musculus with 4 samples.

How the data were processed

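Single-cell RNA sequencing of lung cells from C57BL/6 mice was analysed in 4 libraries, 1 per group: PBS, PBS+RT, LPS and LPS+RT. Per the labels, PBS or 200 µg LPS was given into the trachea, the chest received 1 Gy of X-rays on the next day in the RT groups, lungs were taken at 48 hours, and mononuclear cells were enriched on a Ficoll gradient of grade 1.084 with a target of 10000 cells in the 10x 3' kit of version 3.1. The labels do not say how many mice went into a library. The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.0.1, per the file headers. Cell Ranger 7, R 4.2.2, Seurat 4.3.0 and the mouse genome build mm10 are named in the submitters' processing notes. Whether reads in introns were counted is not stated there. The tables hold 32285 genes. Gene positions are from GENCODE release M21 on that build, found for 32235 genes.

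Everything below was computed from those counts with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9. Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored in each library with a reimplementation of Scrublet (30 components, an expected rate of 8%), and the threshold was the minimum between the modes of the simulated scores. The PBS library had no such minimum and received the median threshold of the other 3, a choice made once this was seen. Removed doublets were 102 (1.13%) in PBS, 96 (1.51%) in PBS+RT, 110 (1.20%) in LPS and 143 (1.44%) in LPS+RT. Of the simulated doublets, only 10.0% in PBS, 19.7% in PBS+RT, 11.8% in LPS and 12.3% in LPS+RT scored above the threshold. Most real doublets may therefore remain among the cells, in shares that differ by library. The cells of all 4 libraries were clustered together without batch correction, on 2000 variable genes, 30 components and 15 neighbors, with the Leiden method at resolution 1.5, giving 54 clusters.

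Clusters were named from markers of 26 classes written before the data were examined. A name needed at least 3 markers in at least 10% of the cells and at least 2-fold above the other clusters. The thresholds of the naming rule were set after the clusters had been inspected, and the rule was revised once, so 2 versions of it were seen. The merging of dendritic classes was also decided then. 8 clusters stayed unnamed: 2 for few UMIs, 5 for markers of more than 1 class and 1 for too few markers. The names are rebuilt from markers and are not the submitters' own annotation.

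Shares are given of leukocytes or of all cells, with exact Clopper-Pearson intervals. For expression, UMIs were summed per library and class and divided by the class total (CPM), in classes with at least 100 cells in both libraries. The ratio of a pair of libraries has an exact conditional binomial interval of 95%. A gene at 0 counts was put at a floor of 3 counts for a fold, and the fold is then a lower bound. No test was made, because cells of 1 library are not replicates. Each of 20 gene lists (251 genes), fixed before the data were examined, is described by the median log2 ratio of members with at least 5 CPM in the higher library, where at least 5 were measured. Its percentile is its place among 10000 random lists of the same size matched on expression in 25 bins. In these medians a member at 0 counts in 1 library takes a value of less than 1 count, and medians that move by more than 0.1 with the floor instead are given both ways, which holds for 2 medians. All 732 medians were computed and seen, and 105 were then chosen for description, so the alternatives below cover only the chosen ones.

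Genes are named by a rule fixed before the data were examined. In each comparison, the 5 classes or fewer with the most cells, each with at least 200 in both libraries, give the 3 genes with the highest and the 3 with the lowest log2 ratio after adding 10 CPM to both values. These genes have at least 50 CPM and 30 UMIs in the higher library, are no mitochondrial, ribosomal protein, hemoglobin or immunoglobulin gene and no marker of another class, and stand at no less than 1/5 of their level in any other class of that library. For each described list, 2 to 4 members with at least 20 CPM and the largest differences are named as well, and Cdkn1a, Mdm2, Il1b, Tnf and Cxcl2 always. 1 gene that the rule picks is not reported here. S100a8 and Sftpc are outside the rule and were chosen to measure RNA of other cells.

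The interval and list steps were tested on counts simulated for endothelial-like cells in LPS+RT against LPS, with 10605 genes of which 200 had a known difference. The intervals held the true ratio in 95.2% of genes. The counts were drawn from a Poisson distribution, the counting error that the intervals assume, so a value near 95% was built in. No spread between cells, clusters or animals was simulated. Of the 67 genes set at 1.5-fold, 91.0% had an interval beyond 0 in the true direction, and at 2-fold and 4-fold 100% had. The lowest percentile among 40 lists of 20 doubled genes was 100. These lists were drawn from the same doubled genes and overlap, so the simulation checks the calculation only.

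15 alternatives were planned before the data were examined. They are a strict cell filter (at least 1000 UMIs, 500 genes, at most 5% mitochondrial UMIs), no filter beyond 200 genes, doublets kept, Leiden resolution 3 (79 clusters), each cell's own highest marker score, TMM size factors, totals without mitochondrial, ribosomal, hemoglobin and immunoglobulin genes, the mean of per-cell CPM, members with at least 50 CPM and all members with at least 1 UMI, some of them for more than 1 kind of result. 8 were added after the data were seen. These leave out the low-UMI neutrophil cluster 15, the endothelial cluster 8 or the cycling macrophage cluster 42, remove from each gene the median log2 ratio of genes of like span, or leave out in turn each cluster of a class where at least 50 cells stay in both libraries and keep the value that moves most.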

Results

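Mouse lungs were profiled by droplet single-cell RNA sequencing in 4 libraries, 1 for each combination of intratracheal PBS or lipopolysaccharide (LPS, a bacterial cell wall component that sets off acute lung inflammation) with or without low-dose X-ray irradiation of the chest. LPS was given at 200 µg per mouse, irradiation (RT) at 1 Gy on the next day, and lungs were taken 48 hours after the injection, 24 hours after irradiation. The libraries are called PBS, PBS+RT, LPS and LPS+RT. They held 10083, 6708, 9572 and 10996 barcodes with 65995600, 69119644, 80013887 and 78669568 UMIs (unique molecular identifiers, each marking 1 captured RNA molecule). After filtering and doublet removal, 8937, 6249, 9029 and 9774 cells remained, with a median of 4300, 8590, 5589 and 4350 UMIs per cell. With 1 library per group there are no replicates, so no difference below has a replicate check and no test was made. Intervals are exact 95% intervals that cover counting error only. Levels are CPM, the UMIs of a gene scaled to the total of its class. Classes are named from marker genes as "-like". Values without a cluster come from splits chosen after the results had been seen.

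The comparison of LPS with PBS shows the inflamed lung without irradiation. Neutrophil-like cells, the first phagocytes to enter an inflamed lung, were 55.7% (54.4 to 56.9) of leukocytes in the LPS library and 3.15% (2.48 to 3.94) in the PBS library, 17.7-fold higher (14.0 to 22.6). Alveolar macrophage-like cells, the resident phagocytes of the airspace, were 2.91% against 27.5%, 9.43-fold lower (7.99 to 11.2), and of all cells 3.52-fold lower (2.98 to 4.17). Genes induced by interferon-gamma were higher in the LPS library in every class described here: their median log2 ratio was 1.65 in endothelial-like cells of blood vessels, 2.49 in fibroblast-like cells, 3.40 in alveolar macrophage-like cells, 3.15 in classical monocyte-like cells, 2.13 in T cell-like cells and 1.80 in B cell-like cells. Each of these medians lay at percentile 100 of 10000 random lists matched on expression.

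Shares of leukocytes depend on the preparation, a Ficoll gradient of grade 1.084 meant to enrich mononuclear cells, on the gap in depth between the libraries, and on the neutrophils themselves, whose higher share in LPS lowers every other share. Classical monocyte-like cells were 10.4% of leukocytes in LPS and 4.4% in PBS, 2.37-fold higher (1.92 to 2.94). Cluster 18, with Saa3 and Nos2 at the top, held 541 of them in LPS and 0 in PBS. Its monocyte marker score was 1.53, against 3.08 for cluster 27. Cluster 27, which held all of them in PBS, was 1.25% of all cells in LPS and 1.14% in PBS. The higher share thus rests on cluster 18. T cell-like cells were 9.11% against 16.6%, B cell-like cells 7.16% against 24.8% and NK cell-like cells 5.48% against 8.50%, while interstitial macrophage-like cells were at 4.38% and 4.53%. The direction turns with the denominator. Of all cells, T cell-like cells were 1.47-fold (1.29 to 1.68), NK cell-like cells 1.73-fold (1.45 to 2.07) and interstitial macrophage-like cells 2.59-fold higher (2.06 to 3.28) in LPS, and B cell-like cells 1.29-fold lower. With each cell named by its own highest marker score, the log2 ratio of the interstitial macrophage-like share of leukocytes was 0.98 in place of -0.05 and that of the alveolar macrophage-like share -2.59 in place of -3.24. Of all cells, endothelial-like cells were 7.57% in LPS and 23.4% in PBS, fibroblast-like cells 4.98% and 11.5%, alveolar type 1-like cells 1.20% and 4.2%, and platelet-like barcodes 2.50% and 11.7%. By own score the log2 ratios were -0.98 in place of -1.63 for endothelial-like and -1.57 in place of -2.23 for platelet-like. Clusters left unnamed held 16.2% of the PBS cells, 11.2% of PBS+RT, 12.0% of LPS and 18.3% of LPS+RT.

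**Figure D1:**
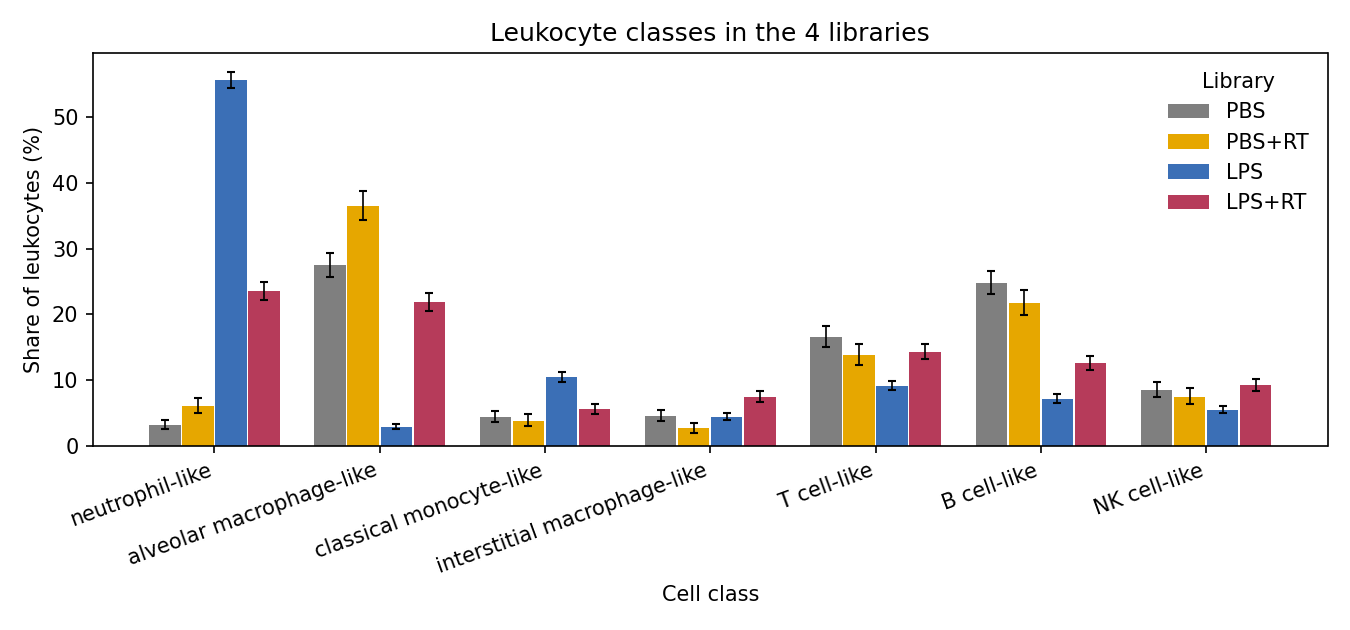
Bars give the share of leukocytes (%, vertical axis) held by each of 7 classes (horizontal axis) in the 4 libraries, and the black lines are exact 95% binomial intervals, which cover counting error only. Neutrophil-like cells stand at 55.7% in LPS and 23.5% in LPS+RT, and alveolar macrophage-like cells at 2.91% and 21.8%.

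In endothelial-like cells, 9 of the 11 measured interferon-gamma response genes were at least 1.5-fold higher in LPS and none was as much lower. Gbp5 (ENSMUSG00000105504, chromosome 3, 142493978 to 142522344, mm10), a guanylate-binding GTPase, was at 92.0 against 13.3 CPM, 6.91-fold higher (5.82 to 8.22). Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), a chemokine that attracts T cells, was at 36.8 against 0.29 CPM, and Cxcl10 at 126 against 14.7 CPM. The type I interferon list had a median of 0.71 there (percentile 100, 9 of 16 members at least 1.5-fold higher), led by Zbp1 and Rsad2. All 7 measured genes of MHC class II antigen presentation were higher (median 1.94, percentile 100), with the invariant chain gene Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652) at 734 against 85.1 CPM. Read from S100a8 and S100a9, RNA of other cells made up as much as 7.61% of the RNA in these droplets in LPS. Its part in the MHC class II values was not computed. The list of adhesion molecules for leukocyte entry did not stand apart (median -0.06, percentile 46.6), and its sign depended on the setting. Dissociation and immediate early genes were lower (median -0.63, percentile 0, 7 of 12 at least 1.5-fold lower).

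Beyond the lists, the histone gene Hist1h1b was 32.5-fold higher (21.6 to 51.1) in endothelial-like cells of LPS, with its 317 UMIs there in 36 of 683 cells. At resolution 3, a small cluster with this gene at the top held 43.2% of them in 21 cells, and without it the gene was 23.4-fold higher (14.7 to 39.3). This split was chosen after the value had been seen. The collagen gene Col18a1 was 11.5-fold higher (8.75 to 15.3). Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), a cytochrome P450 induced through the aryl hydrocarbon receptor, was 27.4-fold lower (20.3 to 38.0), at 8.0 against 219 CPM. Sox18, an endothelial transcription factor, was 2.66-fold lower and Gm26532 2.98-fold lower. Endothelial-like cells lay in other proportions of clusters in LPS. Cluster 2 held 39.9% of them in PBS and 16.3% in LPS, cluster 4 23.4% and 37.9%, and cluster 8 6.37% and 18.2%. A split into the 4 clusters with at least 50 cells in both libraries was chosen after the values had been seen. Inside them the interferon-gamma median was 1.42 to 2.43, the MHC class II median 1.13 to 2.41, and Sox18 was 1.82-fold to 3.11-fold lower. The dissociation median was 0.056 inside cluster 8. Long genes were higher and short genes lower in LPS than in PBS, with medians of 0.30 over 75609 bp and -0.33 up to 8707 bp in endothelial-like cells and 0.46 and -0.36 in B cell-like cells. Alveolar macrophage-like cells had no such trend (0.04 and -0.041). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the p53 target that encodes the cell cycle inhibitor p21, had 583 CPM in LPS and 870 in PBS, a log2 ratio of -0.58 (-0.63 to -0.52), and Mdm2, which encodes the negative regulator of p53, had 78.8 and 73.2 CPM. The NF-kB list of inflammatory cytokines and chemokines had a median of 1.35 in these cells, but its leading members Ccl3, Cxcl2 and Il1b are neutrophil genes: endothelial Cxcl2 was at 265 CPM against 23868 in neutrophil-like cells of the same library, and S100a8, a neutrophil marker, at 1.99% of its neutrophil level, so RNA of neutrophils in the droplets can account for values of this size. RNA of alveolar type 2 cells was also found in these droplets, with Sftpc at 84.8 CPM in LPS and 157 CPM in PBS and the surfactant list at -0.16 (percentile 22.6).

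In fibroblast-like cells of LPS Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), a serum amyloid A gene, was at 1971 against 8.58 CPM, 230-fold higher (181 to 296). Tnc, which encodes the matrix protein tenascin-C, was 18.6-fold higher (16.6 to 21.01) and the B cell chemokine gene Cxcl13 was at 152 against 0.88 CPM. Scara5 was 6.07-fold, Serpinf1 4.82-fold and Pi16 4.46-fold lower. These 3 are top genes of cluster 28, which held 14.9% of the class in PBS and 8.44% in LPS. Without it their log2 ratios were -0.50, -0.18 and 0.73, with intervals that include 0, and that of Cxcl13 was 1.56, so these values rest on that cluster. The log2 ratio of Saa3 was 10.0 without cluster 28 in place of 7.84, and that of Tnc 2.81 without cluster 12 in place of 4.22. The NF-kB list had a median of 2.02 (percentile 100, 16 of 17 members at least 1.5-fold higher), with Ccl3 and Cxcl2 in front, 2 genes of neutrophils, whose S100a8 stood here at 2.85% of its neutrophil level. Iigp1, an immunity-related GTPase, was at 862 against 79.9 CPM.

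T cell-like cells too lay in other proportions of clusters. Cluster 24, with Ifng at the top, held 17.4% of them in PBS and 39.3% in LPS, and cluster 14, with Lef1 at the top, 58.1% and 37.9%. Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047), a cytokine that acts on epithelium, had 1697 UMIs in LPS (297 CPM) and 1 in PBS (0.29 CPM), a ratio of 1007 (181 to 39812). Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), which encodes interferon-gamma, was 30.6-fold higher (22.5 to 42.7) at 370 against 12.1 CPM, and the chemokine gene Xcl1 17.4-fold higher. In a split chosen after these values had been seen, Ifng was 14.4-fold higher inside cluster 24 and 22.9-fold inside cluster 21. Xcl1 was 6.32-fold higher inside cluster 24. Cluster 21 held 1696 of the Il22 UMIs. It scored 3.21 for T cell markers and 2.4 for those of group 2 innate lymphoid cells, so innate lymphoid cells may be among its cells. St8sia6, Gm11290 and Cd40lg were 3.68-fold, 2.75-fold and 2.97-fold lower. Of the cytotoxic effector list 7 of 10 genes were at least 1.5-fold higher (median 0.71, percentile 99.9), of the inhibitory receptor and regulatory T cell list 6 of 10 (median 0.70, percentile 99.8), with Il2ra at 255 against 41.9 CPM, and of the naive and memory list 4 of 8 were at least 1.5-fold lower (median -0.50, percentile 0.02), among them S1pr1 and Ccr7. Inside clusters 14, 21 and 24 the cytotoxic medians were 0.32, 0.63 and -0.45 and the naive and memory medians -0.031, -0.76 and -0.50. These list values rest in part on the mix of clusters. Without cluster 21 the inhibitory receptor and regulatory T cell median was 1.63, and the Il2ra log2 ratio was 6.22 in place of 2.61. In B cell-like cells Serpina3g and Nlrc5, both interferon-responsive, were 4.97-fold and 3.88-fold higher, and Pycard, Myadm and Gm11290 were 4.90-fold, 4.39-fold and 4.06-fold lower. Without cluster 5, which leaves cluster 25, the Pycard log2 ratio was -5.01 in place of -2.29. Cluster 25 scored 3.61 for plasma cell markers and 3.07 for B cell markers. At resolution 3 Pycard was a top gene of a plasma cell-like cluster of 48 cells. Plasma cells in this class may weigh on Pycard in every comparison, which was not tested.

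Among the myeloid classes, different clusters held most cells of the 2 libraries. Alveolar macrophage-like cells of PBS lay mainly in cluster 6 (87.0%) and those of LPS in cluster 16 (75.4%), and classical monocyte-like cells in cluster 27 in PBS (100%) and 18 in LPS (82.7%). In alveolar macrophage-like cells the NF-kB list had a median of 1.5 (percentile 100, 14 of 16 members at least 1.5-fold higher). Cxcl3, a neutrophil-attracting chemokine gene, was at 1253 against 12.6 CPM, Il1b at 710 against 175 and Cxcl2 at 1206 against 469. S100a8 in these cells was at 162 CPM in LPS (1.25% of its neutrophil level) and 65.8 in PBS. RNA of neutrophils can therefore add to these values. The classical activation list was higher (median 1.29, but 1.93 among members with at least 50 CPM and 0.65 with all members), as were glycolysis and hypoxia genes (median 0.93, 10 of 14, with Slc2a1 and Hk2) and cell cycle genes (median 1.29, 17 of 20, with Mki67 at 382 against 55.1 CPM), each at percentile 100. The cycling cluster 42 held 3.3% of the class in PBS and 18.6% in LPS. The cell cycle median was 1.37 without it, but -0.51 without cluster 6, so it depends on which clusters are compared. The NF-kB median was 0.76 without cluster 6. Efferocytosis and cholesterol efflux genes had a median of 0.10 (percentile 68.6), with Abcg1, Mertk and Axl lower, and the sign of the median depended on the expression limit. Dissociation genes were lower here too (median -0.72).

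Classical monocyte-like cells of LPS were higher in the NF-kB list (median 3.06, 17 of 17 members), the classical activation list (median 2.21, or 1.75 with members at 0 counts set to the floor of 3 counts) and the oxidative stress list under NRF2 (median 2.17, 9 of 10). Nos2, which encodes inducible nitric oxide synthase, was at 529 CPM in LPS and had no UMI in PBS, at least 265-fold higher against the floor of 3 counts, and the heme oxygenase gene Hmox1 was at 858 against 48.0 CPM. Without cluster 18 the NF-kB median was 1.81, the classical activation median 1.48, the NRF2 median 0.44 and the interferon-gamma median 2.26. Glycolysis and hypoxia genes had a median of 1.35 there, and 0.23 without cluster 18, and 1.24 in interstitial macrophage-like cells. The latter lay in clusters 20 and 35, with 45.7% and 54.3% of them in PBS and 74.9% and 25.1% in LPS, and had a median of 5836 UMIs per cell in PBS and 21415 in LPS. In them the alternative activation list was lower (median -2.50, 8 of 11 at least 1.5-fold lower, and -3.15 among members with at least 50 CPM), with the scavenger receptor gene Cd163 at 4.09 against 268 CPM and Retnla at 2.49 against 77.6, while Arg1, the arginase gene of the same list, was at 201 against 3.15 CPM. MHC class II genes were also lower in this class (median -1.95, 7 of 8, and -1.29 with each cell weighted equally). Without cluster 20 the MHC class II median was 2.53, with the opposite sign, and the alternative activation median -1.82. The injury list of alveolar type 1-like cells had a median of -0.09 (percentile 40.3), although its member Lcn2 was at 471 against 5.64 CPM, a gene that neutrophils also make. In platelet-like barcodes Retnla, Apod and Taco1 were higher, Myl4 was lower, and Cyp1a1 and Myl7 had no UMI in LPS, at least 10.3-fold and at least 10.2-fold lower against the floor of 3 counts. Cluster 7 held 57.3% of these barcodes in PBS and 84.1% in LPS, and scored 2.0 for platelet and 1.2 for alveolar type 1 markers. At resolution 3 the unnamed clusters 19 and 20 joined platelet markers with those of alveolar type 1 cells and of fibroblasts. RNA of other cells in this class can therefore weigh on these ratios and on its share.

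The comparison of LPS+RT with PBS+RT shows the difference between LPS and PBS where both lungs were irradiated on the day after the injection. Neutrophil-like cells were 23.5% (22.2 to 24.9) of leukocytes in LPS+RT and 6.07% (5.03 to 7.26) in PBS+RT, 3.87-fold higher (3.18 to 4.75; a log2 ratio of 1.95 that was 1.02 by own marker score), and alveolar macrophage-like cells 21.8% against 36.5%, 1.67-fold lower (1.51 to 1.85). Interferon-gamma response genes, far higher with LPS in lungs that were not irradiated, stood much closer to the PBS+RT level here: the median log2 ratio was -0.18 in endothelial-like (percentile 21.4), 0.17 in fibroblast-like, 0.15 in T cell-like, 0.62 in alveolar macrophage-like and -0.57 in B cell-like cells. Cell cycle genes were higher in alveolar macrophage-like cells, with 20 of 20 members at least 1.5-fold higher (median 2.80, percentile 100, but 1.61 among members with at least 50 CPM and 1.90 without the cycling cluster 42). The NF-kB list of inflammatory cytokines and chemokines was higher in neutrophil-like cells (median 2.24, 11 of 16 members).

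Interstitial macrophage-like cells were 7.47% of leukocytes against 2.63%, classical monocyte-like cells 5.56% against 3.82%, NK cell-like cells 9.25% against 7.47%, T cell-like cells 14.2% against 13.8% and B cell-like cells 12.5% against 21.7% (a log2 ratio of -0.79, and -1.49 with the strict filter), with the gradient and depth limits named above. Cluster 18 held 107 of the classical monocyte-like cells in LPS+RT and 1 in PBS+RT, and cluster 27 was 1.04% and 1.12% of all cells. Of all cells the T cell-like share was 1.34-fold, the NK cell-like share 1.60-fold and the interstitial macrophage-like share 3.67-fold higher. Of all cells, endothelial-like cells were 19.2% and 33.9%, fibroblast-like cells 10.3% and 10.9%, alveolar type 1-like cells 3.95% and 5.47% and platelet-like barcodes 6.46% and 3.39%. The trend over gene length ran the other way here than in PBS+RT against PBS. In endothelial-like cells genes spanning more than 76406 bp had a median log2 ratio of -0.32 in LPS+RT against PBS+RT and genes of up to 8831 bp 0.34, and in alveolar macrophage-like cells the longest genes (over 71816 bp) had -0.48 and the shortest (up to 8891 bp) 0.42, so values for long or short genes move with it.

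**Figure D2:**
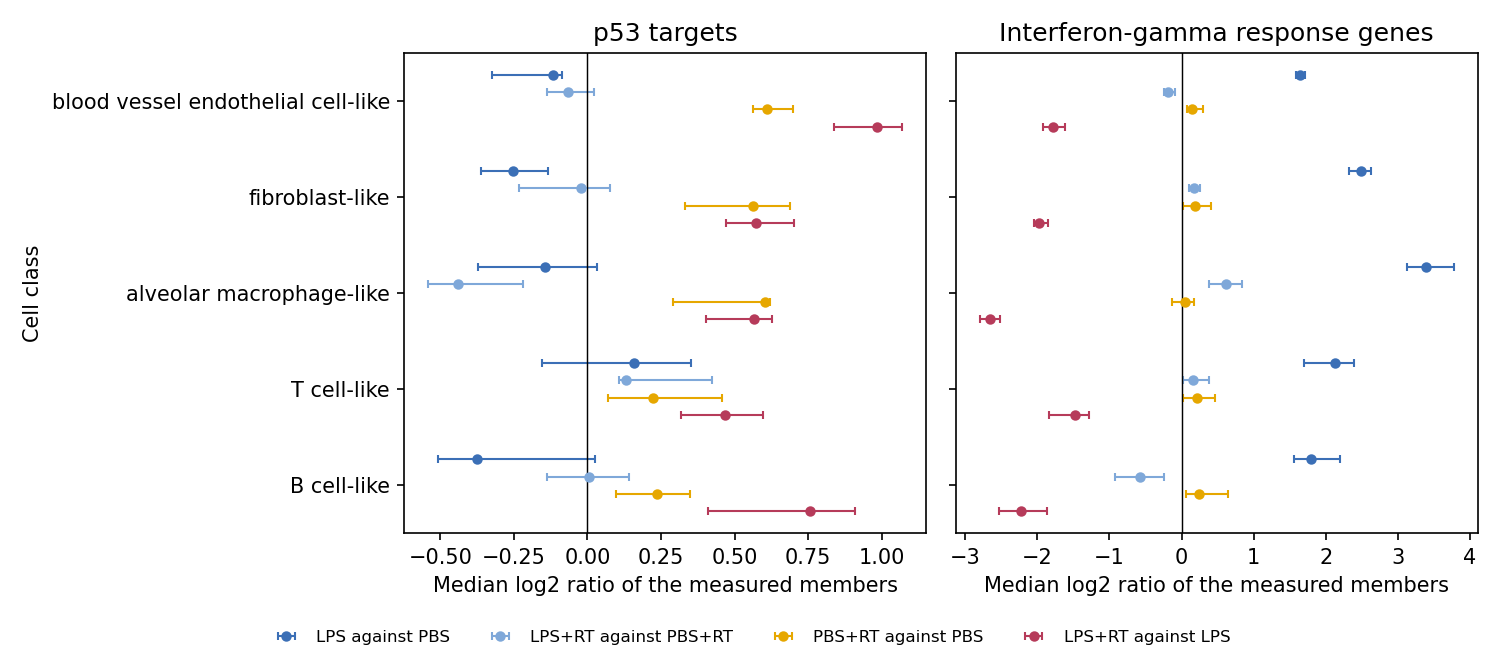
Points give the median log2 ratio (horizontal axes) of the p53 target list and of the interferon-gamma response list in 5 cell classes (vertical axis) for the 4 comparisons, and the lines are 95% counting intervals. The p53 medians of endothelial-like cells are 0.61 and 0.98 in the 2 comparisons of irradiated with other libraries, and the interferon-gamma medians are 1.65 in LPS against PBS and -1.78 in LPS+RT against LPS.

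Alveolar macrophage-like cells of PBS+RT lay in cluster 6 (98.8%), and those of LPS+RT in clusters 16 (64.6%) and 6 (27.8%). Cxcl3 was at 325 against 6.07 CPM in them, 53.5-fold higher (43.9 to 65.8). Wfdc17, and Inhba, which encodes a subunit of activins, were 23.1-fold and 23.2-fold higher. Nav2, Acaa1b and Rbfox1 were 4.37-fold, 3.98-fold and 7.12-fold lower. The NF-kB list had a median of 0.55 (percentile 99.9, 8 of 16 members at least 1.5-fold higher), which was 0.03 once the trend with gene span was taken out, so it rests on that trend. Il1b was at 368 against 221 CPM and Cxcl2 at 1115 against 520, while Tnf was at 52.4 against 91.2. Glycolysis and hypoxia genes were higher (median 1.00, 9 of 14, with Pgam1 and Eno1), MHC class II genes were higher (median 1.34, 4 of 7), as was S100a8 RNA in these cells (79.4 against 16.0 CPM), and p53 targets lower (median -0.44, percentile 1.26).

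Neutrophil-like cells were mostly in cluster 1 in LPS+RT (60.0%) and in cluster 19 in PBS+RT (69.0% of 113 cells). All 9 measured granule protein genes of immature neutrophils were at least 1.5-fold lower in LPS+RT (median -2.03, percentile 0), with Ngp at 2110 against 12847 CPM and Camp at 2287 against 11477. Cluster 48, with Camp and Ngp at the top, held 13.3% of the class in PBS+RT and 2.04% in LPS+RT. The median was -2.69 without it and -0.77 without cluster 1. The activation and ageing list was higher (median 1.67, 8 of 10), led by Ccl3 at 4363 against 162 CPM, as were the NF-kB list (median 2.24, 11 of 16) and the NRF2 list (median 2.89, or 1.92 with members at 0 counts set to the floor and 1.80 with each cell weighted equally). Without cluster 1 these 3 medians were 0.65, 1.16 and 1.06. Il1b was at 7480 and 6745 CPM, a log2 ratio of 0.15 that turned to -0.66 when each cell had equal weight. The p53 list was also higher (median 0.95, 12 of 20), with Cdkn1a at 702 against 153 CPM and Mdm2 at 591 against 157, a log2 ratio of 1.91 that was 0.45 without cluster 1.

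In fibroblast-like cells Saa3 was 15.1-fold higher (13.3 to 17.2), at 482 against 31.9 CPM, the complement gene Cfb 4.3-fold and the monocyte chemokine gene Ccl2 3.98-fold higher, and the NF-kB list had a median of 1.73 (13 of 17; 1.03 among members with at least 50 CPM and 0.91 with each cell weighted equally). Part of that list, Ccl3, Cxcl2 and Il1b, is abundant in neutrophils, with S100a8 in these cells at 0.798% of the neutrophil level. Nr3c2, Kcnt2 and Syn3 were each lower, by 3.14-fold, 3.10-fold and 3.04-fold. Without cluster 12 the Saa3 log2 ratio was 7.48 in place of 3.92. Endothelial-like cells were higher in Depp1 (3.01-fold), Atp13a3 (2.22-fold) and the cyclin gene Ccnd1 (1.98-fold) and lower in Cyp26b1 (3.51-fold), Pard3bos1 (3.18-fold) and 9630028H03Rik (2.78-fold). Icam1, which encodes an adhesion molecule for leukocytes, was at 811 against 501 CPM, and the adhesion list had a median of 0.12 (percentile 86.1). The NF-kB list had a median of 1.10 (10 of 13), led by Cxcl2 at 69.0 against 10.2 CPM and Il1b at 42.7 against 9.98, both abundant in neutrophils. Iigp1 was at 363 against 708 CPM; it is a top gene of the endothelial cluster 8, which held 37.9% of the class in PBS+RT and 13.6% in LPS+RT, and without that cluster the interferon-gamma median was 0.04. Their p53 list was level between these irradiated libraries (median -0.06, percentile 55.7), with Cdkn1a at 1490 and 1295 CPM and Mdm2 at 122 and 112, and the same held in fibroblast-like (median -0.02) and B cell-like cells (median 0.01). The B cell-like median was -0.37 without cluster 5.

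T cell-like cells of LPS+RT were higher in cytotoxic effector genes (median 0.72, percentile 100, 6 of 10), with Gzma at 325 against 112 CPM (medians of 0.17 and 2.28 inside clusters 14 and 21), and lower in naive and memory genes (median -0.41, percentile 2.33). Il22 had 3 UMIs in LPS+RT (0.70 CPM) and 10 in PBS+RT (3.77 CPM), and Ifng was at 26.2 against 15.5 CPM. In B cell-like cells the heat shock genes Hspa1a and Hspa1b were 4.75-fold and 2.83-fold higher and Pycard 1.99-fold higher, while Slc15a2, Agbl1 and Insyn2b were 3.07-fold, 2.34-fold and 2.39-fold lower. In alveolar type 1-like cells Tnnt2, Tubb5 and Nme1 were higher by 3.62-fold, 2.47-fold and 2.47-fold, and Plat, which encodes tissue plasminogen activator, was at 3.67 against 85.4 CPM, with 9530026P05Rik and Mid1 also lower. The ratios of Plat, Mid1 and Tnnt2 were nearer 0 with each cell weighted equally, and without cluster 44 those of Plat and Mid1 were -1.28 and 0.59. Their injury list had a median of 0.37 (percentile 94.2), and near 0 with the span trend taken out. Cell cycle genes in endothelial-like cells had a median of 0.44 (percentile 99.6).

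The comparison of PBS+RT with PBS shows irradiation alone. Targets of p53, the transcription factor that answers DNA damage, were higher in the PBS+RT library in endothelial-like cells (median log2 ratio 0.61, counting interval 0.56 to 0.70, percentile 100, 12 of 21 members at least 1.5-fold higher and none as much lower). The same list had medians of 0.60 in alveolar macrophage-like, 0.56 in fibroblast-like and 0.62 in alveolar type 1-like cells, and of 0.24 in B cell-like and 0.22 in T cell-like cells, where it lay at percentiles 72.4 and 62.9. Cell cycle genes were lower in alveolar macrophage-like cells in 20 of 20 members (median -1.90, percentile 0, but -0.96 among members with at least 50 CPM and -0.91 without the cycling cluster 42).

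Eda2r (ENSMUSG00000034457, chromosome X, 97333840 to 97377216), a receptor of the tumor necrosis factor family, led the p53 list in endothelial-like cells at 52.5 against 3.77 CPM, 13.9-fold higher (10.5 to 18.8). Gdf15 (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456), a stress-induced cytokine gene, was 4.25-fold higher (log2 ratio 2.09, 1.85 to 2.34), Sesn2 3.58-fold and Ephx1 2.44-fold. Cdkn1a was at 1295 against 870 CPM, 1.49-fold higher, and Mdm2 (ENSMUSG00000020184, chromosome 10, 117688875 to 117710758) at 112 against 73.2, 1.53-fold higher. In fibroblast-like cells Cdkn1a was at 369 against 213 CPM and Eda2r at 39.8 against 5.55, and in alveolar macrophage-like cells Cdkn1a was at 738 against 486 CPM, Mdm2 at 168 against 89.4 and Ccng1 at 128 against 66.3. Alveolar type 1-like cells had 255 against 110 CPM of Cdkn1a.

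**Figure D3:**
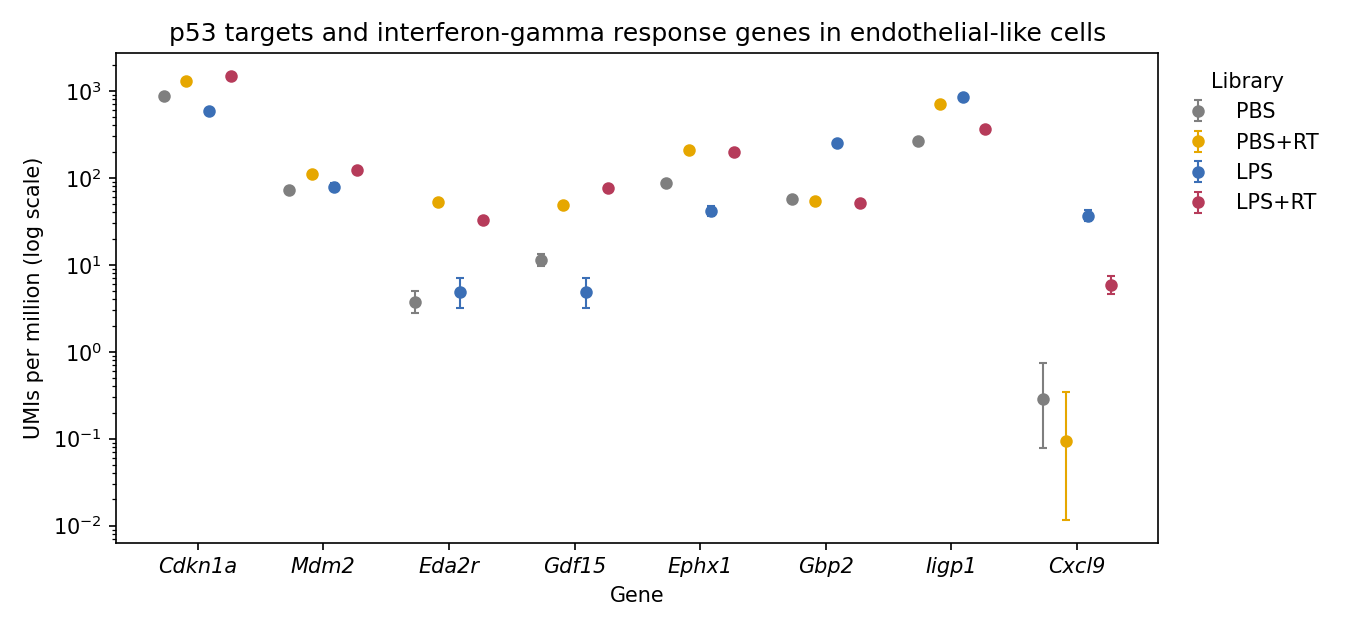
Points give the level of 8 genes (horizontal axis) in endothelial-like cells of the 4 libraries, in CPM on a log scale (vertical axis), and lines are exact 95% Poisson intervals that cover counting error only. Eda2r stands at 52.5 and 32.6 in the irradiated libraries and at 3.77 and 4.83 in the others, and Gbp2 at 252 in LPS and at 51.9 in LPS+RT.

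Long genes were higher and short genes lower in PBS+RT than in PBS in each of 5 classes examined: genes of more than 76124 bp had a median log2 ratio of 0.43 and genes of up to 8774 bp -0.52 in endothelial-like cells, and with near limits the values were 0.56 and -0.51 in fibroblast-like cells and 0.30 and -0.43 in alveolar macrophage-like cells. Among the genes with the largest ratios, Exoc4 (chromosome 6, 33249085 to 33973979) was 3.85-fold higher in endothelial-like and 3.67-fold higher in fibroblast-like cells, and Egfem1 (chromosome 3, 29082023 to 29691209) and Plcb1 were 3.88-fold and 2.85-fold higher in alveolar macrophage-like cells. All 3 are long. Dglucy was 6.13-fold higher (5.23 to 7.23) in endothelial-like cells, Gm15726 9.01-fold and Tnc 4.24-fold higher in fibroblast-like cells, and Taco1 4.3-fold higher in alveolar macrophage-like cells. With the trend over span taken out the endothelial p53 median was 0.85.

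Cyp1a1 was 15.7-fold lower (14.0 to 17.8) in endothelial-like cells of PBS+RT, at 13.9 against 219 CPM, with Atp13a3 3.17-fold and the tubulin gene Tuba1a 2.64-fold lower. Cyp1a1 was also low in LPS, at 8.0 CPM. Its folds in PBS+RT against PBS and in LPS against PBS thus rest on the same PBS library. Spon2, Manf and Serpinh1, the last a collagen chaperone, were 2.80-fold, 2.33-fold and 2.19-fold lower in fibroblast-like cells. In alveolar macrophage-like cells Stmn1, Top2a and Mki67, genes of dividing cells, were 5.38-fold, 4.65-fold and 3.65-fold lower, and the cycling cluster 42 held 2 such cells in PBS+RT and 21 in PBS. MHC class II genes were lower there as well (median -1.94, 6 of 7), at levels of 32.6 against 163 CPM for Cd74. S100a8 was also lower there, at 16.0 against 65.8 CPM, and Sftpc was not (81.6 against 56.3 CPM), so the part of other cells' RNA in these low levels stays open. The NF-kB list had a median of 0.15 (percentile 80.6), with Tnf at 91.2 against 50.3 CPM, and a higher one with the span trend taken out. Endothelial-like cells were level in the interferon-gamma list (median 0.14, percentile 78.9), the adhesion list (median 0.03, percentile 48.0) and the dissociation list (median -0.13, percentile 25.4, and 0.24 with the span trend removed), and lower in cell cycle genes (median -0.48, percentile 1.45), though far less so once the trend over span was taken out. Within the first of these Iigp1 was at 708 against 268 CPM; it is a top gene of cluster 8, which held 6.37% of the PBS class, and without that cluster the median was -0.04. Their surfactant list, which holds alveolar type 2 genes that can come from free RNA here, was lower (median -1.61, 7 of 9), with Sftpc at 51.2 against 157 CPM.

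B cell-like cells were higher in Slc15a2 (3.66-fold), Pvt1 (2.88-fold) and Gm15987 (2.48-fold) and lower in Crip1 (2.08-fold), Pycard (2.13-fold) and Tmsb10 (1.98-fold). T cell-like cells were lower in cytotoxic effector genes (median -0.75, percentile 0, 6 of 10), including Prf1 and the chemokine gene Ccl5, and less so with the span trend taken out. S100a8 was lower in the same cells, at 10.6 against 121 CPM, so RNA of other cells can differ here too. The median was -0.20 inside cluster 14 and -1.39 inside cluster 21. In alveolar type 1-like cells Plat was at 85.4 against 3.22 CPM, Ankfn1 and 9530026P05Rik were 6.27-fold and 3.61-fold higher, and Tnnt2, Myl7 and Npw were 4.93-fold, 2.78-fold and 2.30-fold lower, with the ratios of Plat and Tnnt2 nearer 0 when each cell had equal weight, and Plat at 1.24 without cluster 44. Myl7 was at 68.5 CPM in these cells of PBS and at 60.8 CPM in its platelet-like barcodes. Which cells its RNA came from was not tested. Of leukocytes, neutrophil-like cells were 6.07% against 3.15% (1.93-fold higher, 1.42 to 2.62), alveolar macrophage-like cells 36.5% against 27.5% (1.33-fold higher), interstitial macrophage-like cells 2.63% against 4.53%, T cell-like cells 13.8% against 16.6% and B cell-like cells 21.7% against 24.8%, while classical monocyte-like (3.82% and 4.4%) and NK cell-like cells (7.47% and 8.50%) had ratio intervals that include 1. Of all cells the B cell-like and T cell-like shares were level (1.01-fold, 0.884 to 1.15, and 0.953-fold, 0.811 to 1.12). Of all cells, endothelial-like cells were 33.9% and 23.4%, alveolar type 1-like cells 5.47% and 4.2% and platelet-like barcodes 3.39% and 11.7%, and fibroblast-like cells 10.9% and 11.5%. PBS+RT had the highest median depth and the fewest cells, and shares may differ for that reason alone.

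The comparison of LPS+RT with LPS shows irradiation in the inflamed lung. Neutrophil-like cells were 23.5% of leukocytes against 55.7%, 2.37-fold lower (2.20 to 2.55), and alveolar macrophage-like cells 21.8% against 2.91%, 7.49-fold higher (6.38 to 8.84). Of all cells the folds were 4.28 lower and 4.14 higher, and by own marker score the log2 ratio of the neutrophil-like share of leukocytes was -2.00 in place of -1.24. Interferon-gamma response genes were lower in LPS+RT in all classes described: medians were -1.78 in endothelial-like, -1.98 in fibroblast-like, -2.65 in alveolar macrophage-like, -2.90 in neutrophil-like, -2.96 in classical monocyte-like, -2.26 in dendritic-like, -1.48 in T cell-like and -2.23 in B cell-like cells, each at percentile 0. The classical monocyte-like median was -2.08 without cluster 18 and the fibroblast-like median -2.61 without cluster 12. The p53 list was higher in endothelial-like cells (median 0.98, counting interval 0.84 to 1.07, percentile 100, 16 of 21 at least 1.5-fold higher, none as much lower), as in the comparison without LPS.

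In endothelial-like cells Gdf15 was at 76.2 against 4.83 CPM, 15.8-fold higher (10.7 to 24.3), Ephx1 4.77-fold higher (4.16 to 5.49), and Eda2r at 32.6 against 4.83 CPM. Cdkn1a was at 1490 against 583 CPM, 2.56-fold higher, with a log2 ratio of 1.35 (1.30 to 1.41), and Mdm2 at 122 against 78.8 CPM. Esm1, which encodes the endothelial proteoglycan endocan, was 5.90-fold higher and Hist1h1b 18.6-fold lower (11.6-fold, 8.09 to 17.0, without the small cluster named above). The p53 medians of other classes were 0.57 in alveolar macrophage-like and fibroblast-like, 0.76 in B cell-like, 0.47 in T cell-like and 0.35 in neutrophil-like cells, all above percentile 99, and 0.05 in alveolar type 1-like cells (percentile 55.9). Bax, a pro-apoptotic p53 target, was 2.20-fold higher (1.77 to 2.74) in B cell-like cells, and Cdkn1a was at 37.9 against 14.6 CPM there, at 460 against 176 in fibroblast-like and at 430 against 175 in alveolar macrophage-like cells.

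On the interferon side, Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008) was at 51.9 against 252 CPM in endothelial-like cells, 4.85-fold lower (4.41 to 5.33), Gbp4 was 4.98-fold lower, and 10 of the 11 members were at least 1.5-fold lower. The type I interferon list had medians of -0.71 in endothelial-like, -1.59 in neutrophil-like and -2.47 in dendritic-like cells. MHC class II genes were lower in endothelial-like cells (median -2.49, 7 of 7), with Cd74 at 79.8 against 734 CPM, and higher in interstitial macrophage-like cells (median 1.38, 7 of 8, but 0.086 without cluster 20). In T cell-like cells Ifng was 14.1-fold lower (11.7 to 17.2), at 26.2 against 370 CPM, Il22 had 3 UMIs (0.70 CPM) against 1697 (297 CPM), and Gbp5 was 7.21-fold lower, while S100a4, St8sia6 and Rgcc were 2.40-fold, 2.55-fold and 2.26-fold higher. Cluster 24, with Ifng at the top, held 39.3% of the T cell-like cells in LPS and 20.5% in LPS+RT, and cluster 14 held 37.9% and 47.6%. Ifng was 9.07-fold lower inside cluster 24 and 9.92-fold inside cluster 21. Cytotoxic effector genes were lower (median -0.52) and naive and memory genes higher (median 0.49, with Ccr7 and S1pr1). Inside clusters 14, 21 and 24 the cytotoxic medians were -0.12, -0.30 and 0.16. The naive and memory medians were 0.11, 0.69 and 0.27. B cell-like cells were lower in Irf1 and Nlrc5 (3.68-fold and 3.96-fold) and higher in Pycard (4.57-fold) and Gm11290 (2.87-fold). Without cluster 5 the Pycard log2 ratio was 4.74 in place of 2.19. Neutrophil RNA in endothelial-like cells was less abundant in LPS+RT, with S100a8 at 28.2 CPM against 257 in LPS, while Sftpc was level at 81.9 and 84.8. The part of other cells' RNA in the lower endothelial MHC class II values was not computed.

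Neutrophil-like cells lay mainly in cluster 1 in both libraries (60.0% and 60.1%), but cluster 22, with interferon-induced genes at the top, held 12.4% of them in LPS and 1.47% in LPS+RT. Cxcl10, Gbp5 and Gbp2 were 23.3-fold, 24.9-fold and 11.0-fold lower in LPS+RT. Without cluster 22 the interferon-gamma median was -1.65 and the type I interferon median -0.41. Camp and Ngp, granule protein genes of immature neutrophils, were 3.96-fold and 3.76-fold higher and Gpnmb 4.17-fold higher, with the granule list at a median of 1.00 (percentile 100, 5 of 8), but 0.053 with each cell weighted equally. Cluster 48 held 0.43% of the class in LPS and 2.04% in LPS+RT. Without it the granule median was -0.23, with the opposite sign, while Camp was at 1.41 and Ngp at 3.74. Gpnmb was at -0.23 without cluster 1. The activation and ageing list had a median of -0.58 (5 of 10 lower) although Cxcr4, a receptor of ageing neutrophils, was at 343 against 111 CPM, and the NF-kB list a median of -0.71 (9 of 16 lower), with Il1b at 7480 against 10883 CPM, Cxcl2 at 14039 against 23868 and Tnf at 227 against 355.

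Alveolar macrophage-like cells of LPS+RT were lower in the NF-kB list (median -0.45, 7 of 16), with Cxcl3 at 325 against 1253 CPM and Il1b at 368 against 710. S100a8 RNA in these cells was lower too, at 79.4 against 162 CPM. Cxcl2 was at 1115 and 1206 CPM, a log2 ratio of -0.11 whose sign depended on the scaling. Cell cycle genes were lower (median -0.53, 8 of 20) and efferocytosis genes higher (median 0.51, 4 of 8, with Abcg1 and Mertk). The cycling cluster 42 held 18.6% of the class in LPS and 7.67% in LPS+RT, and cluster 6 held 6.01% and 27.8%. Without cluster 42 the medians were -0.56 and 0.47. Classical monocyte-like cells, of which cluster 18 held 82.7% in LPS and 51.2% in LPS+RT, were lower in the classical activation list (median -0.47), with Nos2 at 36.4 against 529 CPM, and in the NRF2 list (median -0.57, with Hmox1, but 0.066 without cluster 18). Interstitial macrophage-like cells were higher in alternative activation genes (median 0.41, 5 of 11 higher and 2 lower), with Retnla and Cd163 in front, and lower in cell cycle genes (median -1.85, 18 of 20, and -1.12 among members with at least 50 CPM and -0.39 without cluster 20). Fibroblast-like cells were higher in Igfbp3 (4.13-fold), Scara5 (3.82-fold) and Galnt15 (4.31-fold) and lower in Cxcl13 (14.8-fold, less with the strict filter), Chl1 (28.6-fold) and Rbfox1 (14.3-fold), and in the NF-kB list (median -0.99), whose neutrophil genes can come from free RNA. Without cluster 28 Scara5 was at -0.76, Cxcl13 at 0.17 and Rbfox1 at -1.06, so these ratios rest on that cluster. In endothelial-like cells dissociation genes were higher (median 0.83, percentile 100, 10 of 12), with Hspa1b and Hspa1a in front, and in alveolar type 1-like cells the injury list had a median of -0.01, and -0.64 with each cell weighted equally.

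Classical monocyte-like cells were 5.56% of leukocytes against 10.4%, interstitial macrophage-like 7.47% against 4.38%, T cell-like 14.2% against 9.11%, B cell-like 12.5% against 7.16% and NK cell-like 9.25% against 5.48%. Apart from the monocytes, these higher shares depend on the denominator, which holds fewer neutrophils in LPS+RT. Of all cells the folds were 0.944 (0.796 to 1.12) for interstitial macrophage-like, 0.866 (0.768 to 0.976) for T cell-like, 0.969 (0.85 to 1.11) for B cell-like and 0.935 (0.803 to 1.09) for NK cell-like cells. Within the classical monocyte-like class, cluster 18 was 1.09% of all cells in LPS+RT and 5.99% in LPS, and cluster 27 was 1.04% and 1.25%. Of all cells, endothelial-like cells were 19.2% against 7.57%, fibroblast-like 10.3% against 4.98%, alveolar type 1-like 3.95% against 1.20% and platelet-like barcodes 6.46% against 2.50% (a log2 ratio of 1.37, and 0.65 by own score). These shares carry the same limits of the gradient and of depth, and 1 library per group cannot separate irradiation from how strongly each lung had responded to LPS.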

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

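The results below were picked by a rule that asks for opposite directions of the same difference at the 2 levels of the other factor. The values are differences between 2 log2 ratios. With 1 library per group, whether the paired differences differ from each other was not tested.

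Interferon-gamma response genes had medians of opposite sign with LPS. In endothelial-like cells the median log2 ratio was 1.65 without irradiation and -0.18 with it, a difference of -1.83, and in B cell-like cells 1.80 and -0.57, a difference of -2.37. Read by irradiation, the endothelial medians were 0.14 without LPS and -1.78 with it, a difference of -1.93. The endothelial values of -0.18 and 0.14 are near 0 and turn to 0.037 and -0.038 without cluster 8, so the opposite signs there rest on that cluster. These differences were not tested.

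For irradiation, the NF-kB list in alveolar macrophage-like cells had medians of 0.15 without LPS and -0.45 with LPS, a difference of -0.60, and the dissociation list in endothelial-like cells -0.13 and 0.83, a difference of 0.96, although the first is 0.24 with the span trend removed and then has the sign of the other. For LPS, the adhesion list in endothelial-like cells had -0.06 without irradiation and 0.12 with it, a difference of 0.17 between values near 0, and the first turns to 0.28 with all members with at least 1 UMI. None of these was tested.

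Shares of leukocytes had opposite signs too, and the difference was not tested for any of them. The denominator is 55.7% neutrophil-like in LPS, so the shares of all cells are given beside them. With irradiation, the log2 ratio of the neutrophil-like share of leukocytes was 0.95 without LPS and -1.24 with LPS (difference -2.19), of the interstitial macrophage-like share -0.78 and 0.77 (difference 1.55; of all cells -0.58 and -0.08), of the B cell-like share -0.19 and 0.81 (difference 1.00; of all cells 0.009 and -0.05, and the first share of leukocytes is 0.26 with the strict cell filter) and of the T cell-like share -0.27 and 0.65 (difference 0.91; of all cells -0.07 and -0.21). With LPS, the NK cell-like share had -0.63 without irradiation and 0.31 with it (difference 0.94), but of all cells 0.79 and 0.68, both higher. Of these, the neutrophil-like share alone has opposite signs by a wide margin in both denominators (1.15 and -2.10 of all cells). The platelet-like share of all cells differed by 3.15 whichever factor is read: -1.79 and 1.37 for irradiation, -2.23 and 0.93 for LPS. This class may hold barcodes mixed with other cells, as described above.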

How the results depend on the processing

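The alternatives that remove the trend with gene span or leave out a cluster were chosen after the results had been seen, and the others before the data were examined. No paired analysis was possible because each group is a single library. Values are log2 ratios, and the cause of these moves was not tested.

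A value is called reversed where its main counting interval excludes 0 and the alternative has the opposite sign. Of 224 share values under an alternative, 1 was reversed, of 766 list medians 16 were, and of 3210 gene ratios 36 were. The reversed share was that of B cell-like cells in PBS+RT against PBS, at 0.26 with the strict cell filter. Values whose main interval includes 0 can change sign without being counted. The interstitial macrophage-like share of leukocytes in LPS against PBS, at -0.05, was 0.98 by own score.

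The neutrophil-like share in LPS+RT against LPS was -1.24, and -1.06 with the strict filter, -1.42 with no filter beyond 200 genes, -1.58 at Leiden resolution 3, -2.00 by each cell's own highest marker score and -1.41 without the low-UMI neutrophil cluster. In LPS+RT against PBS+RT it was 1.95, and 1.5 at resolution 3 and 1.02 by own score. The alveolar macrophage-like share was -3.24 in LPS against PBS (strict filter -3.74, own score -2.59), -0.74 in LPS+RT against PBS+RT (-1.09 and -0.46) and 2.90 in LPS+RT against LPS (own score 2.49). The directions held under these settings.

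Among the lists, the adhesion median in endothelial-like cells, LPS against PBS, had the opposite sign with all members with at least 1 UMI (0.28), the mean of per-cell CPM (0.27) and the trend with gene span removed (0.074). The efferocytosis median in alveolar macrophage-like cells, LPS against PBS, was -0.46 among members with at least 50 CPM. Without the endothelial cluster mostly of the PBS+RT library, the interferon-gamma median was 0.037 in LPS+RT against PBS+RT and -0.038 in PBS+RT against PBS, and the dissociation median in PBS+RT against PBS was 0.24 with the span trend removed. The interferon-gamma median in endothelial-like cells, LPS against PBS, was 1.5 among members with at least 50 CPM, 1.76 with the span trend removed and 1.35 without that cluster. The NF-kB median in alveolar macrophage-like cells, LPS+RT against PBS+RT, was 0.55, and 0.64 with TMM size factors but 0.034 with the span trend removed. The endothelial p53 medians were 0.85 in PBS+RT against PBS and 0.79 in LPS+RT against LPS with that trend removed.

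Cdkn1a in endothelial-like cells kept its direction under every setting run. Without the cluster it was -0.88 in LPS against PBS, 0.29 in LPS+RT against PBS+RT, 0.46 in PBS+RT against PBS and 1.62 in LPS+RT against LPS. With TMM it was 0.25 in LPS+RT against PBS+RT and 1.43 in LPS+RT against LPS, with totals without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes 0.24 in LPS+RT against PBS+RT and 0.53 in PBS+RT against PBS, and with the mean of per-cell CPM 0.23 in LPS+RT against PBS+RT. Ratios reversed under the mean of per-cell CPM were Cxcl2 in endothelial-like cells (-0.017) and Il1b in fibroblast-like cells (0.10) for PBS+RT against PBS, Il1b in neutrophil-like cells (-0.66) and Irf1 in fibroblast-like cells (-0.087) for LPS+RT against PBS+RT, and Vegfa in interstitial macrophage-like cells (-0.064) for LPS against PBS. Cxcl2 in alveolar macrophage-like cells, LPS+RT against LPS, was 0.024 with TMM and 0.051 with the strict filter.

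With each cluster of a class left out in turn and the largest move kept, medians reversed in the sense above in LPS against PBS were adhesion in endothelial-like cells (0.40), cell cycle (-0.51) and efferocytosis (-0.24) in alveolar macrophage-like cells and MHC class II in interstitial macrophage-like cells (2.53). In LPS+RT against PBS+RT they were the interferon-gamma list in endothelial-like (0.037) and T cell-like cells (-0.16), in PBS+RT against PBS dissociation in endothelial-like cells (0.12), and in LPS+RT against LPS the granule list in neutrophil-like cells (-0.23) and NRF2 in classical monocyte-like cells (0.066). Medians with a main interval that includes 0 changed sign as well. In LPS against PBS these were surfactant in endothelial-like (0.013) and injury in alveolar type 1-like cells (0.31). In LPS+RT against PBS+RT they were p53 targets in endothelial-like (0.049) and B cell-like cells (-0.37). Adhesion in endothelial-like cells (-0.21) did so in PBS+RT against PBS, and injury in alveolar type 1-like cells (0.11) in LPS+RT against LPS. The endothelial interferon-gamma median was then 2.13 in LPS against PBS and -1.58 in LPS+RT against LPS, the endothelial p53 median 0.80 in PBS+RT against PBS, and the NF-kB median in alveolar macrophage-like cells 0.25 in LPS+RT against PBS+RT.

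Under this setting endothelial Cdkn1a was -0.88, 0.014, 0.80 and 1.62 in the 4 comparisons in the order of the report. Genes reversed in the same sense in LPS against PBS were Pi16 in fibroblast-like cells (0.73), Vcam1 in endothelial-like cells (0.64), Tnf (-0.098) and Rrm2 (-0.28) in alveolar macrophage-like cells, and H2-Eb1 (2.84), H2-Aa (2.53) and H2-Ab1 (2.87) in interstitial macrophage-like cells. In LPS+RT against PBS+RT they were Il1b (-0.41) and Gdf15 (-0.53) in neutrophil-like cells, Mid1 in alveolar type 1-like cells (0.59), Vcam1 in endothelial-like cells (0.28), Pmaip1 in B cell-like cells (-0.25), and Gbp5 (0.20) and Irf1 (-0.12) in fibroblast-like cells. In PBS+RT against PBS they were Cxcl2 (-0.10) and Vcam1 (-0.11) in endothelial-like cells, Il1b in fibroblast-like cells (0.62), Cxcl2 in T cell-like cells (-2.74) and Pmaip1 in B cell-like cells (0.13). In LPS+RT against LPS they were Scara5 (-0.76) and Cxcl13 (0.17) in fibroblast-like cells, Gpnmb (-0.23), Mdm2 (-0.18) and Gdf15 (-1.90) in neutrophil-like cells, Cdkn1a in T cell-like cells (-0.29), Cxcl2 in alveolar macrophage-like cells (0.052), Gclm in classical monocyte-like cells (0.29), and H2-Ab1 (-0.59) and Top2a (0.22) in interstitial macrophage-like cells.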

Other observations

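The tests of neutrophil depth, of neutrophil loss, of Ifng and of dissociation stress were chosen after the result each measures had been seen, and the gene span test after the span trend had been seen. In all, 10 explanations were tested, and 1 of them, a lower recovery of all leukocytes, was dropped because an equal loss leaves a share of leukocytes as it is and so its outcome was fixed. The first reading of the dissociation test counted its value against that explanation, and it was rewritten as open after the value was seen. A depth test of the p53 pattern was also run and is given with that pattern.

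Ifng in NK cell-like cells followed the T cell-like cells: it was at 452 CPM in LPS, 122 in LPS+RT, 70.2 in PBS and 59.4 in PBS+RT.

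The neutrophil-like share of leukocytes was lower in LPS+RT than in LPS. Among cells of at least 1000 UMIs, 500 genes and at most 5% mitochondrial UMIs the log2 ratio was -1.06, which argues against cells below these cuts as the whole cause. The filter does not make depth equal between the libraries. Neutrophil-like cells had a median of 5106 UMIs in LPS and 3855.5 in LPS+RT. An effect of depth on clustering and naming was therefore not tested. A loss of neutrophils in the preparation of the LPS+RT library cannot be told apart from fewer neutrophils in the lung: S100a8 RNA in B cell-like cells was also lower (log2 ratio -2.20), but a wash can remove cells and their RNA together. In other classes this ratio ran from -3.19 in endothelial-like to -0.46 (-0.80 to -0.13) in NK cell-like cells. S100a8 in NK cell-like cells did not follow the neutrophil-like share, with 191 CPM in PBS and 85.5 in LPS. Their ratio therefore cannot decide the question. A difference in how strongly the lungs responded to LPS stays open and untested.

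Interferon-gamma response genes were lower in LPS+RT than in LPS in endothelial-like cells. RNA of other cells, read from S100a8 and S100a9, gave a median of 13.6% of the members' difference (60.3% for the member most affected). Inside the endothelial clusters with at least 50 cells in both libraries the highest median was -1.41. These values argue against such free RNA and the mix of these clusters as the whole cause. Smaller subsets and remaining doublets were not tested. At resolution 3 the endothelial-like cluster 74, with Ubd and Cxcl9 among its top genes, held 30 cells in LPS and 1 in LPS+RT. A candidate explanation is the lower Ifng level in T and NK cell-like cells, with a log2 ratio of -2.85 (-3.02 to -2.69). It was found and tested on the same libraries, and a difference between animals or libraries in the response to LPS was not tested.

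The p53 targets were higher in both irradiated libraries in endothelial-like cells. The lowest median inside the clusters was 0.70, and the lower of the 2 medians with the trend over gene span removed was 0.79, which argues against cluster mix and gene length. Depth also points the other way: the median was 0.98 in LPS+RT against LPS, where the irradiated library is the shallower. Dissociation stress cannot be told apart from an effect of irradiation, because the lower of the 2 dissociation medians was -0.13 but 0.24 with the span trend removed, and the other was 0.83. The pattern may be a response to irradiation, the factor that both pairs share, as a hypothesis that 1 library per group leaves untested.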
